A study of Mus musculus with 13 samples.

How the data were processed

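Digastric and masseter muscles of C57BL/6J mice were profiled by RNA sequencing. Tumour-bearing mice had received 150000 KPC FC1245 cells, a line from a mouse pancreatic tumour driven by Kras and Trp53 mutations, in 50 µL saline in the tail of the pancreas, and Sham mice had received saline alone. Per the labels' protocols each condition held 8 mice, and poly(A)-selected libraries were made from 250 ng RNA and sequenced as paired reads of 150 bases to at least 40 M reads. The series holds 3 Sham and 3 KPC digastric libraries, and 4 Sham and 3 KPC masseter libraries. The labels do not say that each library of a group came from another mouse, so p-values measure the spread between these libraries. They give neither the sex of the mice nor the day of collection.

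The deposited table, described by its name as normalised counts, holds 23684 genes and 1 column per library. Per the submitters' processing notes FastQC 0.12.1, STAR 2.7.11b, Salmon 1.10.3 and the mm10 build were used, without their roles. The counting step, its use of strand, the annotation release and the source of the size factors are not stated. Tested on the values themselves, the deposited signal in each column is a whole multiple of 1 step, within 0.001 of a whole number for 100% of the values above 0. Each deposited value is therefore a whole number divided by 1 factor per library, and these whole numbers, called reads here, could be recovered. Whether they count single reads, read pairs or rounded estimates is not stated. The table also carries a column of 53 gene symbols with no heading, which was tested only as an extra list, given at the end. A spreadsheet had turned 25 symbols into dates, and these were restored through the gene identifiers. Of the identifiers, 23667 matched GENCODE M21 on mm10, which gave the coordinates.

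Between 44.8 and 60.2 M reads were assigned to genes per library, and the normalised totals ran from 37.6 to 63.5 M counts. At this depth counting error is small for genes well above the minimum given next, and the spread between libraries sets the precision. Genes with a normalised count of at least 10 in at least 3 of the 13 libraries were tested (15988 genes). Values were log2(normalised count + 1). A linear model with 1 mean per group was fitted to all 13 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the text come from this model unless another tool is named. The standard errors beside log2 fold changes are limma's moderated ones, and the errors beside normalised counts are SDs over the libraries of a group. The contrasts were KPC against Sham in digastric and in masseter, the difference of these effects, and masseter against digastric in Sham.

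Before the data were examined, 31 gene lists of pathways and cell types were fixed, along with the tests, the processing alternatives and the rule for the genes that the text names. The lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a set move on balance one way, were alternatives. A list score per library is the median over the list's genes of the log2 value minus the Sham mean of the same muscle. The rule names the 8 largest rises and falls among genes that passed, had a mean of at least 50 and did not overlap between the groups, leaving out predicted genes. It adds up to 4 genes with the smallest p of each list and a fixed panel of genes of muscle wasting, inflammation and contraction. For the difference it names the 10 smallest p, and for the Sham muscles the 6 largest rises and falls and the contractile and head muscle lists. A plot of myosin genes adds Myh1, Myh2 and Myh3 in the Sham muscles, which the panel holds.

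The alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, scaling to equal totals, recomputed size factors, quantile normalisation, a fit on the compared groups alone, robust and weighted fits, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, blocks on replicate numbers, and leaving out each library in turn. After the data were seen, a fit without the KPC digastric libraries 2 and 3 and a fit with the lymphocyte and salivary epithelium scores as covariates were added. Marker lists of lymph node stroma, naive lymphocytes, platelets, reticulocytes and submandibular gland were also written after the main results and before their own tests. Ppbp, Alas2 and Snca had been seen to rise when these lists were written, and Itga2b, Clec1b, Gp9, Treml1, Slc4a1 and Gypa before the lists were tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

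The model was tested on simulated counts with 200 genes changed by 2-fold or 4-fold. In the digastric simulation it recovered 14% of the 2-fold and 70.7% of the 4-fold changes, with 4 false calls among 89. In masseter it recovered 28% and 67%, with 4 false calls among 101. For the difference of the effects it recovered 4% and 49%, with 4 false calls among 57, and for the Sham muscles 23.2% and 74%, with 6 among 103. A simulated shifted list was found in all 4 comparisons. The unshifted list had unadjusted camera p-values of 0.149, 0.319, 0.0382 and 0.512 in the same order. The simulated genes were drawn independently of each other, with 1 dispersion per gene shared by all groups. Correlated genes and groups of unequal spread were not simulated, so these rates need not hold for the measured libraries.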

Results

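The data are gene-level RNA-seq values from 2 muscles of the jaw, the digastric, which opens it, and the masseter, which closes it, in mice with an orthotopic KPC pancreatic tumour and in Sham mice. There were 3 Sham and 3 KPC digastric libraries, with 50.8 to 60.2 and 48.6 to 56.8 M assigned reads (M, mega). For masseter there were 4 Sham and 3 KPC libraries, with 52.4 to 58.3 and 44.8 to 54.8 M assigned reads. Mitochondrial transcripts held 24.5% to 28.9% of the normalised total in Sham digastric, 15.7% to 22.5% in KPC digastric, 16.2% to 19.0% in Sham masseter and 16.0% to 20.2% in KPC masseter. The first principal component, with 45.1% of the variance, set KPC digastric replicates 2 and 3 apart from the other 11 libraries.

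KPC against Sham in the digastric asks which transcripts a pancreatic tumour elsewhere in the body changes in this muscle. Stat3, which carries interleukin-6 family signals to the nucleus, rose from 1951 ± 286 to 4121 ± 402 normalised counts (SD, n = 3 in each group; log2 fold change 1.08 ± 0.14, adjusted p = 0.0077). Of the fixed lists, 5 of 7 erythroid genes rose, and 12 of 32 matrix and 7 of 13 fibroblast genes fell, and none of these lists passed with an estimated correlation. In total 390 genes passed, 106 higher and 284 lower, of which 86 and 191 changed at least 2-fold. Stat3 lies on chromosome 11 from 100885098 to 100939540 (mm10, ENSMUSG00000004040).

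In the list of acute phase and IL-6 to STAT3 response genes, 3 of 19 measured members rose, none fell and 16 did not pass (median log2 fold change 1.00). Besides Stat3 these were Socs3, the feedback inhibitor of the pathway (2.56 ± 0.48, adjusted p = 0.0235), and Bcl3, a co-regulator of NF-κB (2.27 ± 0.39, adjusted p = 0.0183). Adjusted over the list alone, 9 were higher and 1 was lower. The list passed camera with adjusted p = 5.3e-04, and had adjusted p = 0.375 with an estimated correlation. Serpina3n and Lcn2, which belong to it, had log2 fold changes of 3.53 ± 0.98 (adjusted p = 0.0678) and 1.90 ± 1.198 (adjusted p = 0.298).

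Of 7 erythroid genes, 5 rose and 2 did not pass (median 1.51; camera adjusted p = 2.3e-06, adjusted p = 0.375 with an estimated correlation; 7 higher when adjusted over the list alone). Alas2, the first enzyme of haem synthesis in red cells, rose from 357 ± 116 to 1225 ± 197 normalised counts (1.82 ± 0.27, adjusted p = 0.0099). The globin gene Hbb-bs rose from 16150 ± 6544 to 38805 ± 5932 (1.33 ± 0.29, adjusted p = 0.0377). Hba-a1 and Hbb-bt rose by 1.44 and 1.51 on the log2 scale. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies, so how reads fell between them is uncertain. In the neutrophil list, 2 of 10 genes rose (median 1.63; camera adjusted p = 0.0040, adjusted p = 0.375 with an estimated correlation). These were Csf3r, the receptor of the granulocyte growth factor (2.56 ± 0.47), and the chemokine receptor Cxcr2 (4.73 ± 0.99).

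Of 32 genes of fibrillar collagen and matrix, 12 fell and 20 did not pass, with 1 higher and 19 lower when adjusted over the list alone. The list's median log2 fold change was -1.28, with camera adjusted p = 5.7e-09 and adjusted p = 0.375 with an estimated correlation. Col5a2 fell from 1224 ± 162 to 391 ± 73.1 normalised counts (-1.65 ± 0.24, adjusted p = 0.0098). Col6a1, a chain of the collagen around fibres, had a log2 fold change of -1.80 ± 0.30, the gelatinase Mmp2 of -1.43 ± 0.20 and Sparc of -0.97 ± 0.15. Col1a1 and Col3a1 did not pass, at -1.97 ± 0.68 (adjusted p = 0.0992) and -2.44 ± 0.60 (adjusted p = 0.0521). Of 13 genes of fibroblasts and fibro-adipogenic progenitors, 7 fell (median -1.30; camera adjusted p = 1.6e-06, adjusted p = 0.375 with an estimated correlation). Dpt fell from 4004 ± 922 to 982 ± 335 (-2.06 ± 0.28), and Pi16 and Mfap5 both had log2 fold changes of -2.18. The score of the matrix list was -1.78, -0.92 and -1.17 in KPC replicates 1, 2 and 3. Postn of the matrix list went both ways, with 77.9, 1143 and 810 normalised counts in these libraries against 245 to 320 in Sham.

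**Figure D1:**
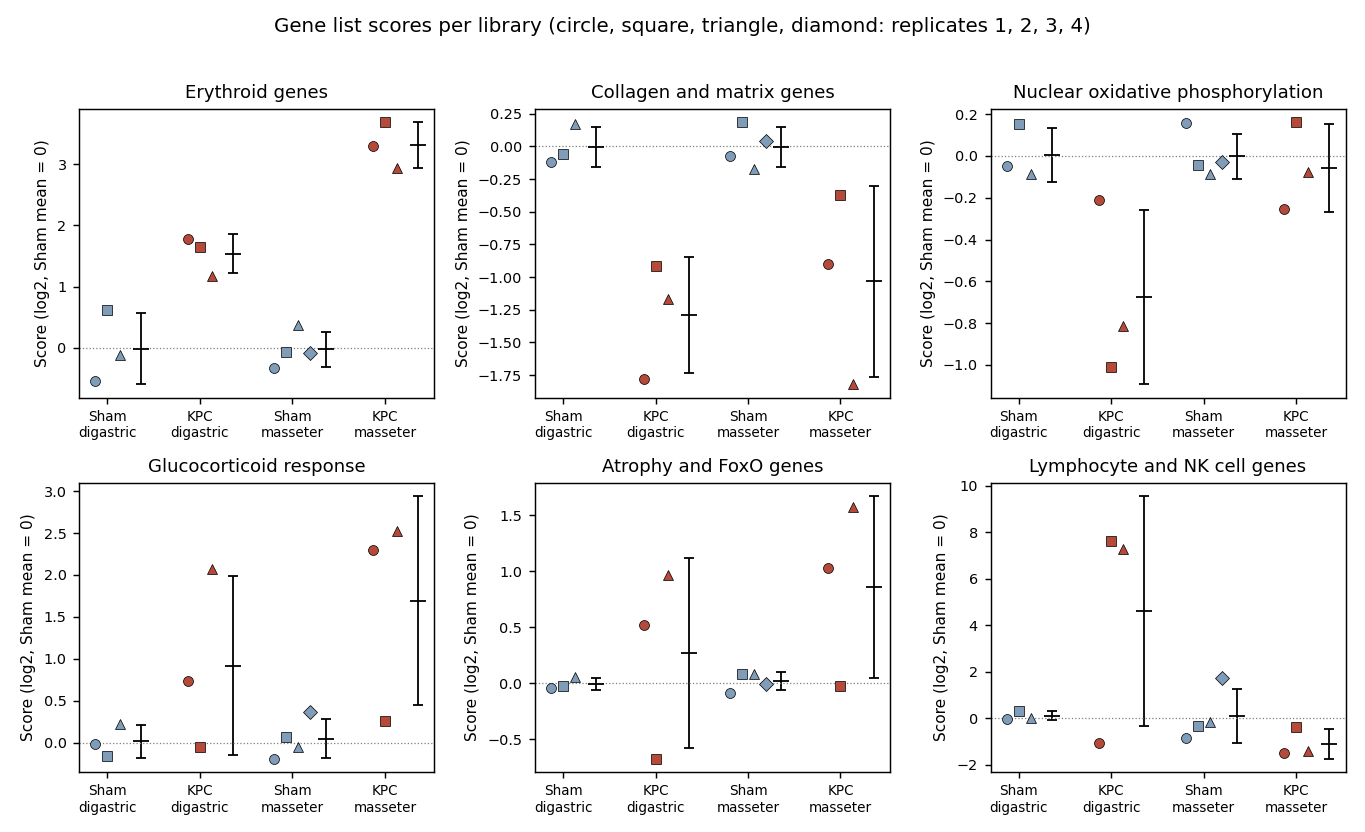
Scores of 6 gene lists per library (y axis, log2, with the Sham mean of the muscle at 0) in the 4 groups, 1 symbol per replicate, with the group mean and SD as a bar beside the symbols. The erythroid score was above and the matrix score below those of all Sham libraries of the muscle in all 6 KPC libraries, and the lymphocyte score was 7.65 and 7.31 in KPC digastric replicates 2 and 3.

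Of 41 nuclear genes of oxidative phosphorylation, 8 fell and 33 did not pass (median -0.68; camera adjusted p = 2.3e-16, adjusted p = 0.456 with an estimated correlation; 35 lower when adjusted over the list alone). Ndufa1 of complex I, Uqcrb of complex III, and Cox7a1 and Cox8b of complex IV had log2 fold changes of -0.85, -0.86, -1.06 and -0.91. The list score was -0.21 in KPC replicate 1, against -1.01 and -0.81 in replicates 2 and 3, which held lymphocyte transcripts. Of the genes chosen by size of fall, Actc1, the cardiac and fetal actin, fell from 14510 ± 4056 to 2201 ± 2139, and the prostaglandin receptor Ptgfr from 129 ± 52.9 to 19.0 ± 5.96. Mfap4, Fhl2, Cd248, Angptl1, Mest and Dupd1 made up the rest, with log2 fold changes from -3.02 to -2.31. The myelin genes Pmp22 and Mpz fell, at -1.12 ± 0.18 and -1.78 ± 0.42, as did Car3 and Fabp4 of the adipocyte list, at -1.31 ± 0.25 and -0.88 ± 0.18.

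The 8 largest rises were Cxcr2, Nfkbid, Unc13d, Sap25, Il4i1, Csf2rb2, Ly6c2 and Apobec3, with log2 fold changes from 4.73 to 3.17, and several of these are expressed by leukocytes. KPC replicates 2 and 3 carried most of these folds, with Il4i1 at 933 and 757 against 42.6 in KPC replicate 1, Unc13d at 562 and 498 against 26.8, and Nfkbid at 244 and 212 against 14.6. Replicate 1 also lay above all Sham libraries for the 8 genes, which the naming rule required, with Cxcr2 at 20.7 against at most 3.40. Without KPC replicates 2 and 3, in a fit chosen after the data were seen, the KPC group rests on 1 library. The 7 genes that could be tested then had log2 fold changes from 0.77 for Il4i1 to 2.92 for Cxcr2. KPC replicates 2 and 3 also held lymphocyte transcripts at levels seen in no other library. Cd19 of B cells stood at 2703 and 2919 normalised counts there, against 15.8 in KPC replicate 1 and 4.53 to 10.2 in Sham (5.96 ± 1.68, adjusted p = 0.0696). Ms4a1 stood at 2198 and 2487 against 9.74 in KPC replicate 1. Genes of a list written for the submandibular gland held 1.15% and 1.05% of the normalised total in KPC replicates 2 and 3. They held 1.09% in Sham replicate 2, against at most 0.0185% in the other digastric libraries. The genes behind these shares differed. Bpifa2 and Amy1 stood at 267661 and 148665 normalised counts in Sham replicate 2, Dcpp1 at 313708 in KPC replicate 2 and Mucl2 at 444453 in KPC replicate 3. Which gland they came from was not tested. None of the 10 measured genes of the lymphocyte list passed over all genes, and 6 were higher when adjusted over the list alone (camera adjusted p = 5.3e-04, adjusted p = 0.469 with an estimated correlation).

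The clock gene Per1 rose (2.43 ± 0.56, adjusted p = 0.0455) and was the gene of the glucocorticoid list that passed, out of 20 (median 0.77; camera adjusted p = 0.0108, adjusted p = 0.6005 with an estimated correlation). Without KPC replicates 1 and 3 in turn this list had camera adjusted p = 0.159 and 0.112. The ubiquitin ligases of muscle wasting did not pass. Fbxo32 had a log2 fold change of 0.66 ± 0.84 (adjusted p = 0.605), with 42074, 8764 and 85320 normalised counts in KPC replicates 1 to 3 against 16293 to 22540 in Sham. Trim63 had 1.08 ± 1.00 (adjusted p = 0.477), with 10832, 3452 and 66961. The glucocorticoid target Fkbp5 stood at 5091, 1479 and 15842, against a Sham range of 1308 to 2086. Slc3a2, an amino acid transporter subunit, rose by 1.12 on the log2 scale, and Atf5 had -0.95 ± 0.20, in a list of stress response genes with 1 rise and 1 fall among 19.

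Groups did not overlap for 25.9% of genes, where chance gives 10%, and the count of 390 rested on single libraries. Without Sham replicates 1, 2 and 3 it was 53, 36 and 4, without KPC replicates 1, 2 and 3 it was 6477, 170 and 66, without both KPC replicates 2 and 3 it was 213 (70 of them among the 390), and it was 7 (3 higher, 4 lower) when libraries were scaled to equal totals. The excess of falls turned with the tool, to 1053 higher and 518 lower by edgeR and 2055 and 1172 by DESeq2, and array weights gave 3770 and 3905. In a limma fit of the digastric groups alone 0 genes passed, and all 45 named calls, Stat3 included, were lost.

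KPC against Sham in the masseter puts the same question to the jaw-closing muscle. The clearest rises were those of red cell genes, with Alas2 11.2-fold and the beta globin gene Hbb-bs 8.72-fold higher. Alas2 rose from 136 ± 28.7 normalised counts (SD, n = 4) to 1538 ± 363 (n = 3; log2 fold change 3.48 ± 0.26, adjusted p = 1.3e-04). Stat3 rose from 2981 ± 235 to 5814 ± 520 (0.96 ± 0.13, adjusted p = 0.0123). Mybph, a myosin-binding protein, fell from 1420 ± 468 to 136 ± 92.1 (-3.54 ± 0.51, adjusted p = 0.0179). In total 50 genes passed, 27 higher and 23 lower, of which 25 and 18 changed at least 2-fold. Alas2 lies on chromosome X from 150547375 to 150570638 and Mybph on chromosome 1 from 134193448 to 134201232 (mm10).

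All 7 erythroid genes rose (median 3.27; camera adjusted p = 8.8e-20, adjusted p = 0.0541 with an estimated correlation). Hbb-bs rose from 5245 ± 920 to 46639 ± 13964, and Hba-a1 from 2530 ± 714 to 24186 ± 5699, with reads again shared between near-identical copies. Slc4a1, the anion exchanger of red cells, rose by 4.50 ± 0.72 from a Sham mean of 5.46, and Snca, which red cells also express, rose by 3.31 ± 0.30. Among the other large rises were Ppbp, a chemokine of platelets (3.49 ± 0.45, from 10.6 ± 6.66 to 114 ± 13.2), and the membrane protein gene Tmem82 (4.05 ± 0.72).

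Of the 32 matrix genes 2 fell and 30 did not pass, with 1 higher and 15 lower when adjusted over the list alone. The list's median was -1.02, with camera adjusted p = 5.2e-12 and adjusted p = 0.447 with an estimated correlation. The 2 were Col5a2, from 901 ± 156 to 400 ± 140 (-1.21 ± 0.22, adjusted p = 0.0483), and Col6a1 (-1.52 ± 0.28, adjusted p = 0.0483). Mmp2 and Loxl2 had log2 fold changes of -0.99 ± 0.19 (adjusted p = 0.0543) and -1.73 ± 0.33 (adjusted p = 0.0512). The matrix score was -0.90, -0.37 and -1.82 in KPC replicates 1 to 3. None of the 13 fibroblast genes passed over all genes, and 6 were lower when adjusted over the list alone (median -0.75; camera adjusted p = 5.2e-05, adjusted p = 0.447 with an estimated correlation). Adra1a, an adrenergic receptor, Smoc2, Pcdh18, Tril and Colgalt2, a collagen galactosyltransferase, were among the largest falls, with log2 fold changes from -1.95 to -1.31. Car3, a muscle and fat carbonic anhydrase, fell from 8669 ± 1320 to 3007 ± 1205.

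In the glucocorticoid list 1 of 20 genes rose, and 16 were higher when adjusted over the list alone (median 1.54; camera adjusted p = 1.4e-12, adjusted p = 0.447 with an estimated correlation). That gene was Per1 (3.02 ± 0.52, adjusted p = 0.0404). Cebpd stood at 5114, 391 and 8099 normalised counts in KPC replicates 1 to 3, against 225 to 453 in Sham. None of the 20 atrophy and FoxO genes passed over all genes, and 1 was lower when adjusted over the list alone (median 0.84; camera adjusted p = 7.8e-06, adjusted p = 0.531 with an estimated correlation). Fbxo32 had a log2 fold change of 1.93 ± 0.78 (adjusted p = 0.268), with 120940, 18097 and 169528 in KPC replicates 1 to 3 and 10630 to 26023 in Sham. Trim63 had 2.43 ± 0.93 (adjusted p = 0.258), with 36182, 6497 and 119898 against 4970 to 5971. Pdk4, which restrains glucose oxidation, had 3.53 ± 0.97 (adjusted p = 0.155), in a list of fatty acid use with no call over all genes (median 0.65; camera adjusted p = 4.6e-08, adjusted p = 0.506 with an estimated correlation). The atrophy score was 1.03, -0.03 and 1.57 in KPC replicates 1, 2 and 3.

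**Figure D2:**
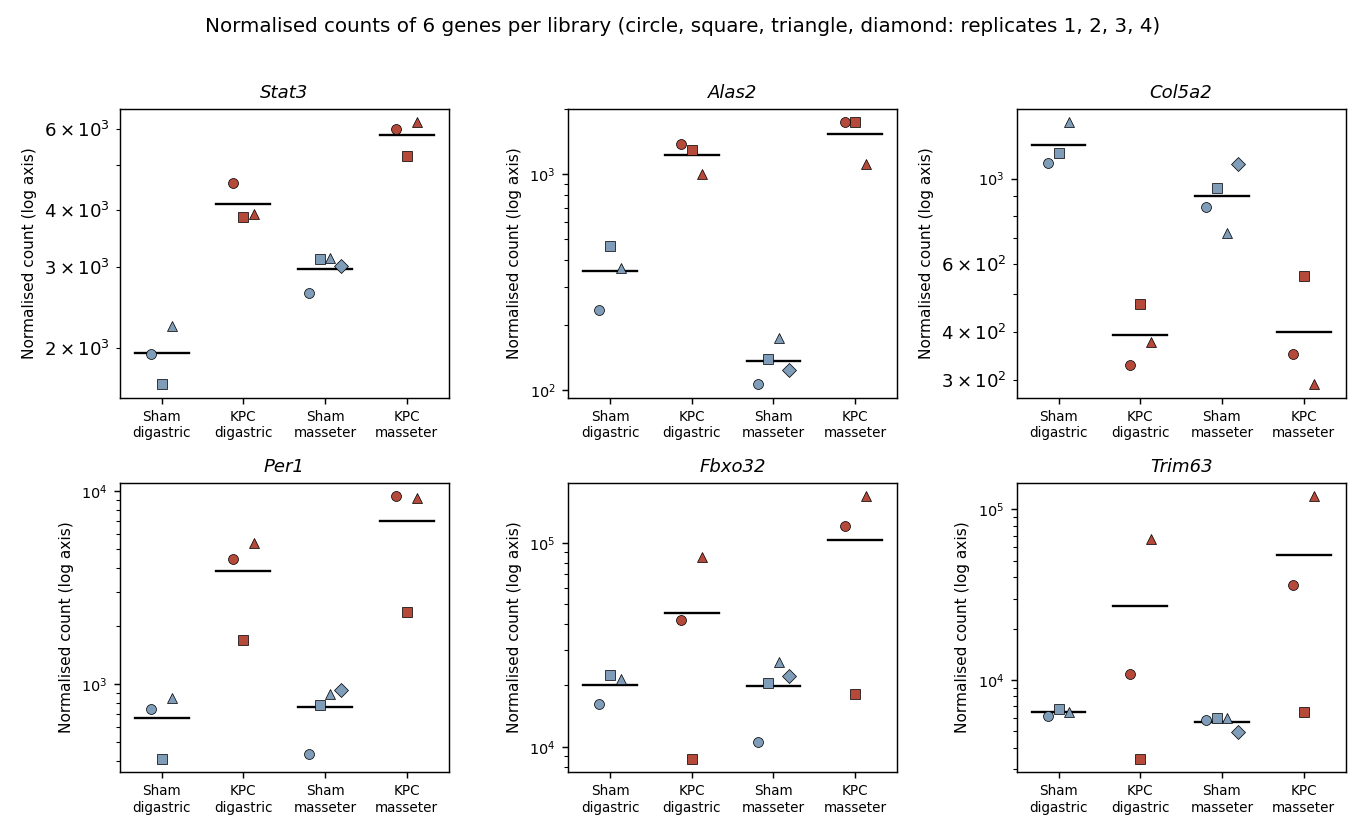
Normalised counts per library (y axis, log) of Stat3, Alas2, Col5a2, Per1, Fbxo32 and Trim63 in the 4 groups, 1 symbol per replicate, with the group mean as a line. All KPC libraries lay above those of the Sham group of the muscle for Stat3, Alas2 and Per1 and below them for Col5a2, while Fbxo32 in KPC masseter was 18097 in replicate 2 and 120940 and 169528 in replicates 1 and 3.

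In the acute phase list Stat3 passed, and 7 genes were higher when adjusted over the list alone (median 0.96; camera adjusted p = 2.9e-06, adjusted p = 0.347 with an estimated correlation). Socs3 had 1.58 ± 0.45 (adjusted p = 0.159). Interferon and antigen presentation genes had a median of -0.51 with no call over all genes (camera adjusted p = 4.8e-06, adjusted p = 0.606 with an estimated correlation), among them Gbp3 at -1.43 ± 0.27 (adjusted p = 0.0537). The score of this list was -0.43, -0.14 and -0.97 in KPC replicates 1 to 3. Nuclear oxidative phosphorylation genes had a median of -0.04 and no call over all genes (camera adjusted p = 0.425, adjusted p = 0.945 with an estimated correlation). By camera at its preset the list passed in the direction of a fall with equal totals (-0.16, adjusted p = 0.0038), after quantile normalisation (-0.20, adjusted p = 1.3e-07) and without KPC replicate 2 (-0.17, adjusted p = 0.0376). These settings were not run with an estimated correlation. The lymphocyte score was -1.50, -0.35 and -1.42 in the KPC libraries.

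Groups did not overlap for 16.8% of genes, where chance gives 5.71% for 4 libraries against 3. The count of 50 was 9, 10, 11 and 18 without Sham replicates 1 to 4, 10 and 10 without KPC replicates 1 and 3, 1802 without KPC replicate 2, and 25 (15 higher, 10 lower) with equal totals, and quantile normalisation gave 20 higher and 7 lower.

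The next comparison asks whether the tumour effect differed between the muscles. No gene passed in the main limma test of the difference, while 1491 had an unadjusted p under 0.05. By edgeR the count was also 0 and by DESeq2 it was 451. Limma called 902 with array weights and 4249 with the library number as a block, though these numbers are not shown to pair the libraries. Among the 10 smallest p-values were Alas2 and Hbb-bs, with masseter effects larger than the digastric ones by 1.67 ± 0.38 and 1.80 ± 0.39 on the log2 scale (both adjusted p = 0.533), and Tet3 at -1.12 ± 0.21 and Gbp5 at -1.48 ± 0.28. The larger red cell effects in masseter started from a lower Sham level. Alas2 stood at 106 to 174 in Sham masseter and 236 to 466 in Sham digastric, but at 1119 to 1749 and 1001 to 1376 in KPC. The erythroid list had a median of -1.47 for masseter against digastric in Sham. Fbxo32 and Trim63 had differences of 1.27 ± 1.15 and 1.35 ± 1.37. By lists, 15 of 31 passed camera and 0 did with an estimated correlation (adjusted p from 0.636 upward). The difference was 0.62 for nuclear oxidative phosphorylation and 1.77 for erythroid genes (adjusted p = 1.6e-17 and 2.2e-08, and adjusted p = 0.699 and 0.636 with an estimated correlation). Without KPC digastric replicates 2 and 3, which held lymphocyte transcripts, the differences were 0.14 and 1.49. That fit was chosen after the data were seen and rests on 1 KPC digastric library.

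Across genes, the log2 fold changes of the muscles had a Pearson correlation of 0.32 and a Spearman correlation of 0.39 over 15988 genes, which are not independent replicates. Of the 106 and 27 rises, 15 were shared, where 0.179 would be shared by independent lists, and of the 284 and 23 falls 14 were shared, against 0.409. Stat3, Per1, Alas2, the globin genes, Snca and Ppbp were among the shared rises, and Col5a2, Col6a1, Car3, Adra1a, Smoc2, Pcdh18, Tril and Colgalt2 among the shared falls. No gene passed in opposite directions. The 2 comparisons have no library in common. They were fitted in the same model, with a spread per gene shared by all 13 libraries, and libraries of the muscles may share mice. The overlap is thus a description, and the counts for independent lists are no test of it. Without KPC digastric replicate 1 the count for the difference was 3135, without KPC masseter replicate 2 it was 1, and the correlation was 0.18 and 0.55 without KPC digastric replicates 1 and 2.

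**Figure D3:**
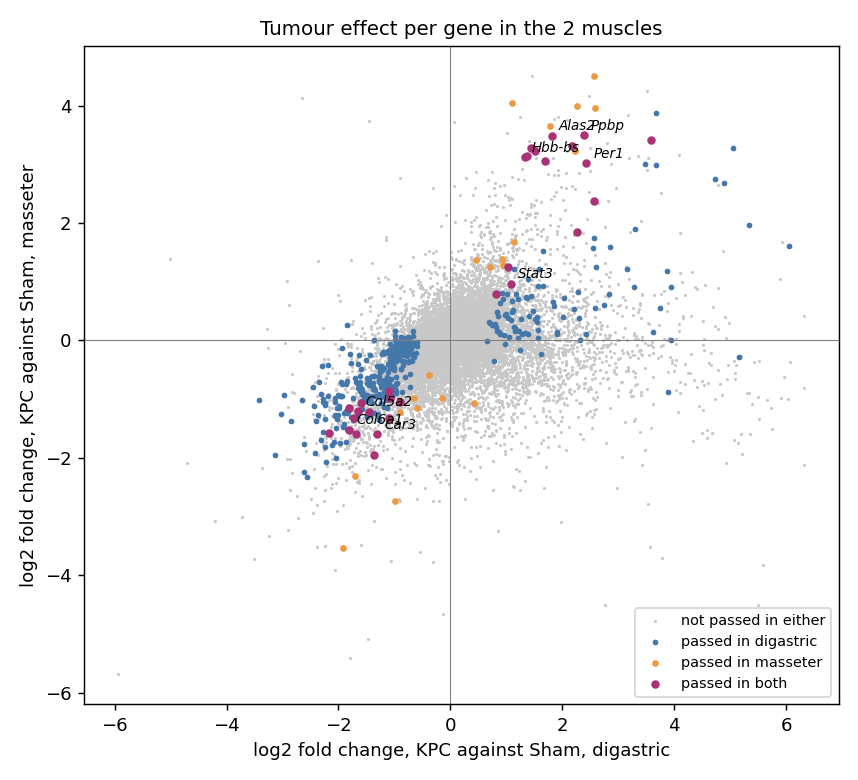
Log2 fold change of each tested gene between KPC and Sham in digastric (x axis) and masseter (y axis), 1 point per gene, coloured by whether it passed in digastric, in masseter or in both. The genes that passed in both, 15 higher and 14 lower, lie in the quadrants of equal sign.

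Masseter against digastric in Sham mice gives the baseline difference of the muscles. The muscles differed in their myosins: Myh8, the perinatal myosin heavy chain, was higher in masseter, at 256260 ± 71200 normalised counts (SD, n = 4) against 868 ± 777 in digastric (n = 3; log2 fold change 8.53 ± 0.46, adjusted p = 1.8e-06). Myh4, the chain of the fastest fibres, was lower in masseter, at 69818 ± 83082 against 356188 ± 50548 (-3.01 ± 0.61, adjusted p = 0.0147), with 193269 in masseter replicate 1 and 20263 to 44744 in the others. Padi2, a protein-arginine deiminase, stood at 90.4 ± 18.8 in masseter and 14739 ± 811 in digastric (-7.36 ± 0.36). In total 620 genes passed, 269 higher and 351 lower in masseter, of which 171 and 281 differed at least 2-fold. Myh8 and Myh4 lie in one cluster on chromosome 11, from 67277124 to 67308634 and from 67238029 to 67260446 (mm10), and they are similar in sequence.

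B3gat1, Vwc2, Camp and Myh13, the extraocular and laryngeal myosin, were higher in masseter, with log2 fold changes from 7.31 to 4.71. Bdh1, a ketone body enzyme, Mettl21e, Sln, an inhibitor of the calcium pump, and the glutamate receptor Grm1 were lower, from -6.55 to -5.68. Nkx2-3 had 192 ± 72.1 in digastric and 0 in all 4 masseter libraries, so it was at least 65.5-fold lower with a floor of 3 reads per library. In the fast-fibre list 3 genes were higher and 1 lower among 19 (median 0.59; camera adjusted p = 4.7e-04, adjusted p = 0.998 with an estimated correlation), with Actn3, Mybpc2 and Myoz1 at 1.28, 1.28 and 1.00. In the slow-fibre list 3 were higher and 3 lower among 16 (median 0.07; camera adjusted p = 0.905). Myh7 and Tnnc1 were higher in masseter, at 106 ± 12.5 and 42.3 ± 17.1, and Myl2 and Myoz2 were lower, at 13.8 ± 13.2 and 2111 ± 887. Actc1 was lower, at 885 ± 652 against 14510 ± 4056.

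**Figure D4:**
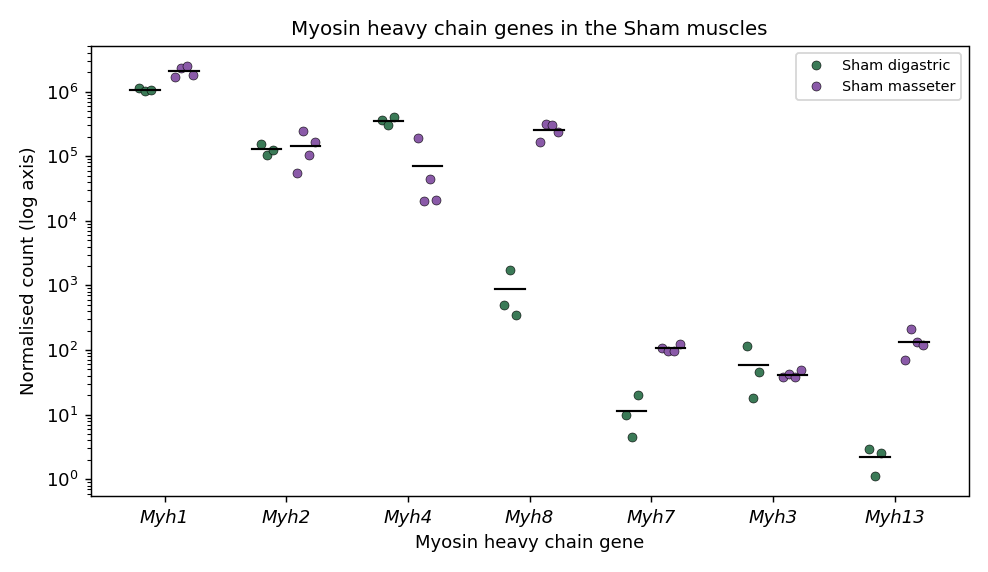
Normalised counts (y axis, log) of 7 myosin heavy chain genes (x axis) in the 3 Sham digastric and 4 Sham masseter libraries, 1 point per library, with the group mean as a line. Myh8 stood at a mean of 868 in digastric and 256260 in masseter.

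Head muscle regulators were split by muscle, with 3 higher and 3 lower among 12 (median -0.10; camera adjusted p = 0.955). Lhx2, a homeobox gene, stood at 1174 ± 172 in masseter against 113 ± 14.9 in digastric (3.36 ± 0.21), and Dlx6 was higher at 10.2 ± 2.74. Lbx1 and Hand2 were lower, at 81.6 ± 14.03 against 646 ± 76.0 and 0.744 ± 0.4995 against 39.5 ± 14.1. In the adipocyte list 6 of 12 genes were lower (median -2.41; camera adjusted p = 1.1e-10, adjusted p = 0.125 with an estimated correlation), and 4 of 32 genes of fatty acid use were lower (median -0.83; camera adjusted p = 1.5e-09, adjusted p = 0.998 with an estimated correlation). In the erythroid list 5 of 7 were lower (median -1.47; camera adjusted p = 1.7e-07, adjusted p = 0.451 with an estimated correlation). Groups did not overlap for 33.9% of genes, where chance gives 5.71%. Without Sham digastric replicates 1, 2 and 3 the count was 325, 260 and 255, and without Sham masseter replicates 1 to 4 it was 394, 399, 346 and 377.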

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

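All tests of explanations and of splits in this part were chosen after their results could be seen, apart from that of the lymph node list. In the 4 Sham masseter libraries, 9 of 98 values tested (list scores, library measures and named genes) had 1 library far from the other 3. Chance marks about 1 in 20 such groups, and the values of 1 library are not independent of each other. In replicate 1, Myh4 stood at 193269 normalised counts against 20263 to 44744 in the others. Actc1 stood at 1849 there against 412 to 639.7, Mettl21e at 83.1 against 9.09 to 17.0, and Myoz1 at 159398 against 116380 to 123617. Replicate 4 had a neutrophil score of 0.87 against -0.54 to -0.31, Slc4a1 at 15.2 against 1.05 to 2.83, and Trim63 at 4970 against 5816 to 5971. Replicate 3 had Mmp2 at 1141 against 1517 to 1575, and Hand2 at 0 against 0.909 to 1.05. The Hand2 values are 0 reads against 1 read in each of the others, so this flag lies at the floor of the counts.

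By camera, 15 lists had tumour effects that differed between the muscles, and none did with an estimated correlation. Effects were higher in masseter for atrophy and FoxO genes (median difference 0.49), proteasome subunits (0.42), autophagy and lysosome (0.33), glucocorticoid response (0.71), nuclear oxidative phosphorylation (0.62) and mitochondrially encoded mRNA (0.77). They were also higher there for fatty acid use (0.66), glycolysis and glycogen (0.37), fibroblasts and progenitors (0.78), erythroid genes (1.77) and tendon and cartilage (0.90). They were lower in masseter for interferon and antigen presentation (-0.85), p53 targets and cell cycle (-1.05), lymphocytes and NK cells (-5.20) and salivary gland and epithelium (-2.11). KPC digastric replicates 2 and 3 stand apart in several of these lists, with p53 and cell cycle scores of 1.92 and 2.21 against -0.29 in replicate 1 and interferon scores of 0.82 and 0.56 against -0.55. A fit without these 2 libraries, also chosen after the data were seen, rests on 1 KPC digastric library, so only effect sizes are given. The differences were 0.15 for proteasome, 0.64 for glucocorticoid, 0.14 for oxidative phosphorylation, 1.42 for fibroblast, 1.49 for erythroid and 1.89 for tendon genes. They were 0.20 for atrophy, 0.11 for autophagy, 0.08 for mitochondrially encoded, 0.21 for fatty acid and -0.17 for glycolysis genes. The differences for interferon, p53, lymphocyte and salivary genes were then -0.03, 0.28, -0.78 and 1.22. With each library left out in turn, 7 of the 15 passed throughout.

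Over the splits of the libraries into groups of the same sizes, the real one gave the most genes for masseter (real 50, highest other 1). The same held for the Sham muscles (real 620, highest other 1). In both, 1 of 35 splits gave as many genes, the smallest share that 35 splits allow. Every other split mixes the compared groups, which widens the spread within them, so these counts do not exclude chance. The 10 splits of the digastric libraries are too few for a share under 0.05, with a real count of 390 and a highest other of 46. For the difference between muscles the real count was 0, which fixes the share, so 100 of 100 drawn splits gave as many. The highest of them called 711 genes. It kept the digastric groups as they were and exchanged 2 of 3 KPC masseter libraries with Sham ones, and what gave its count was not tested.

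Several tests of the patterns weighed next were altered once their first values were known. The lymph node list was first scored on its 7 genes that passed the expression filter, giving 6.95, and then on the 10 in the table. The gland list was first judged by the median of its 11 tested genes, and by the bound set for it this first value spoke against gland tissue. That reading was set aside because a Sham digastric library itself has a gland share of the total near those of the KPC ones. This raises the baseline. The genes behind the shares differed, with Smr3a at 86182 normalised counts in Sham digastric replicate 2 and at 0 in KPC digastric replicates 2 and 3. A second test was then added, and with all 12 gland genes the first would have given 1.28, past that bound. The bound for the share of cells between the fibres was widened from an SD of 0.155 over Sham libraries to 0.838, and then to 1.68, over KPC libraries, and under either earlier bound that explanation would have been set aside.

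Lymphocyte transcripts stood apart in KPC digastric replicates 2 and 3, with scores of 7.65 and 7.31 against -1.08 in replicate 1. Lymph node tissue taken along with the muscle is a candidate source: genes of node stroma and its vessels had a lowest median of 6.77 log2 over Sham in these libraries, and Glycam1 of node vessels stood at 11194 and 9369 normalised counts against at most 4.87 in the other digastric libraries. Lymphocytes carried in by blood are argued against, since the lower erythroid score of the 2 libraries minus that of replicate 1 was -0.60. Salivary gland tissue stays open: its first test gave -0.14, its share of the total and the lymphocyte score had a Spearman rho of 0.886 over 6 libraries, and Sham digastric 2 held 1.09% gland transcripts with a lymphocyte score of 0.33. The gland share sums genes whose mixture differed between the libraries, so it need not stand for the same tissue in each. A larger node or an immune response in tumour-bearing mice was not tested, and the lymphocyte genes cannot be assigned to the muscle.

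The matrix score was below 0 in all 6 KPC libraries, with 12 of 32 genes called lower in digastric and 2 in masseter, and the list passed in neither muscle with an estimated correlation (adjusted p = 0.375 and 0.447). Dilution by lymphoid tissue is argued against by the matrix score in the 4 KPC libraries without lymphocyte transcripts, whose median was -1.34, with all 4 below 0. Scaling between libraries is also argued against, since the matrix median stayed at -0.91 or lower under the 3 scaling alternatives in both muscles. A lower share of all cells between the fibres stays open in masseter: the endothelial median lay 0.92 above the matrix median, beyond the SD of 0.838 over 3 KPC libraries of that difference but within 2 of them. An effect of the tumour on matrix gene expression also stays open, and these values do not separate it from that change of cell share.

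Glucocorticoid and atrophy genes differed between the KPC libraries of a muscle, with Fbxo32 and Trim63 lowest in replicate 2 of each; these 2 libraries carry the same number in their library names, and the labels do not say whether it marks a mouse. Gland or lymphoid tissue is argued against in masseter, because the atrophy score still had a range of 1.60 over the KPC masseter libraries, which held no lymphocyte excess. For digastric it was not tested. There the atrophy score was -0.67 in KPC replicate 2 and 0.97 in KPC replicate 3, which both held lymphocyte transcripts, and 0.52 in replicate 1. The mitochondrial share, taken as a sign of RNA quality, had a Spearman rho of -0.0286 with the atrophy score over the 6 KPC libraries. That rho pools 2 muscles with different Sham shares, so it cannot decide whether RNA quality matters. In replicates 1 to 3 the share was 16.0%, 20.2% and 16.2% in KPC masseter and 22.5%, 15.7% and 19.0% in KPC digastric. Replicate 2, lowest in atrophy score in both muscles, had the highest share in masseter and the lowest in digastric. Time of day stays open, since 8 clock genes had a median range of 1.33 log2 over KPC masseter against 0.837 over Sham masseter. Differences in tumour burden or food intake between mice may also separate the libraries and were not tested.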

How the results depend on the processing

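The fit without KPC digastric replicates 2 and 3, the covariates, and the correlation with 1 library left out were chosen after seeing the data. Under the alternatives fixed before the data were examined no call of a named gene changed direction, while counts of calls moved, and the cause was not tested unless given. Of the named calls, 1 of 45 in digastric (Stat3) and 6 of 20 in masseter (Alas2, Snca and the 4 globin genes) passed whichever library was left out. In the Sham muscles 19 of 25 passed in every such fit that tested them. Among these 19, Hand2 was tested in only 4 of the fits, not in those without a Sham digastric library. The digastric count of 390 became 0 in a limma fit of its own groups (2751 at an unadjusted p under 0.05), which leaves out the spread of the masseter libraries. KPC digastric libraries correlated with each other at 0.848 to 0.937, against 0.954 to 0.988 within the other groups. The digastric count was 7 with equal totals (median of all genes shifted from 0.02 to 0.23 log2) and 1247 after quantile normalisation. It was 3227 by DESeq2 (2055 of them higher), 1571 by edgeR (1053 higher), and 7675 with array weights (3770 higher). It ran from 4 to 6477 with 1 library left out. It was 213 without KPC replicates 2 and 3, where KPC rests on 1 library assumed to vary like the other groups, and 35 with lymphocyte and epithelium scores as covariates. C1qa, at 0.13 and not past the threshold with all libraries, reversed to -2.32 (adjusted p = 0.0493) without replicates 2 and 3.

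The masseter count of 50 became 33 with no filter, 25 with equal totals (median shifted to -0.12), 27 after quantile normalisation, 32 in a fit of its own groups, 9 with array weights and 697 by DESeq2, and ran from 9 to 1802 with 1 library left out. The difference between muscles gave 902 genes with array weights, 451 by DESeq2, and 0 to 3135 with 1 library left out. A fit of the compared groups alone is not possible there, as it needs all 4. The Sham muscle count of 620 became 3652 in a fit of its own groups, 5173 with array weights, 1176 by DESeq2 and 1007 with the covariates, and ran from 255 to 399 with 1 library left out.

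With an estimated correlation 0 lists passed in any comparison. With fry, 8 passed in digastric (20 by camera at its preset; 12 by it after quantile normalisation), 2 in masseter (12 by camera), 0 for the difference (15 by camera) and 2 in the Sham muscles (10 by camera). The correlation of effects of 0.32 was 0.227 with no filter, 0.408 with a minimum of 50, 0.525 without KPC digastric replicates 2 and 3 and 0.460 with the covariates, and ran from 0.179 to 0.545 with 1 library left out.

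With the replicate number in the titles as a replicate block, the count was 135 in digastric, 11 in masseter and 351 in the Sham muscles; with the library number as a block it was 149 in digastric, 4249 for the difference and 1842 in the Sham muscles. The numbers are not shown to pair the libraries by the bar chosen, which was that every pair has a correlation over 0.1. Missing this bar does not show that the libraries are unpaired, since the correlations rest on deviations from means of 3 or 4 libraries. By title number between KPC and Sham 2 of 6 pairs had a correlation over 0.1. By library number between muscles 4 of 5 had one (median 0.158), against 2 of 16 pairs with different numbers (median -0.0491), and 7 of 10 libraries correlated best with their own number, a hint from the data and not from the design. Depth limits genes near the minimum of 10, where counting error is largest.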

Other observations

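All marker lists here were written, and their tests chosen, after the main results were seen. In a list of 8 platelet genes 3 rose in digastric (Ppbp, Itga2b and Clec1b; median of the list 2.32) and 5 in masseter (these, Gp9 and Treml1; median 3.24), and none of the 8 is in the fixed lists. Pf4 went the other way in digastric, at 59.7, 86.7 and 75.8 normalised counts against 119 to 228 in Sham, while Itga2b stood at 194, 359 and 402 against 52.1 to 84.8. The rise of Ppbp was known when the list was written and that of the other 4 before it was tested, so a test of the whole list is not independent of them. With an estimated correlation the unadjusted camera p was 0.0052 in digastric and 2.1e-04 in masseter without Ppbp, 0.0694 and 0.0022 without the 3 genes that rose in both muscles, and 0.465 and 0.0403 for the 3 genes left without all 5. In a list of 9 reticulocyte genes, which shares Alas2, Slc4a1 and Gypa with the erythroid list, 2 rose in digastric (median 0.02) and 4 in masseter (median 0.13). Without those 3 genes and Snca, whose rise was also known, the medians were -0.36 and -0.10. Of the abundant genes of this list, which muscle also expresses, Ank1 stood at 14702, 8338 and 4183 in KPC digastric replicates 1, 2 and 3 against 16368 to 19454 in Sham, and Tfrc at 1430, 2139 and 762 against 3456 to 5611.5. Fech stood at 8732, 3595 and 5188 against 6163 to 7195, and Epb41 at 5711, 3752 and 4136 against 4289 to 4601.

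Of the other marker lists, naive lymphocyte genes had a digastric median of 5.33 (p = 1.3e-05, 0.115 with an estimated correlation) and a masseter median of -0.40 (p = 0.655), with Sell at 3489 and 5276 and Ighd at 4210 and 5787 in KPC digastric replicates 2 and 3. The lymph node list had medians of 4.61 (p = 0.0021, 0.228 with an estimated correlation) and -0.96 (p = 0.484). The gland list, whose 12 genes are all in the fixed lists, had medians of 0.43 (camera p = 0.958) and -2.20 (camera p = 0.0169, 0.304 with an estimated correlation). Bpifa2 stood at 267661 in Sham digastric replicate 2, Dcpp1 at 313708 in KPC digastric replicate 2 and Mucl2 at 444453 in replicate 3. Sham masseter replicate 1 also held gland transcripts, with Bpifa2 at 16328, which raises the Sham mean there. Its gland share was 0.0731% of the total, against at most 0.00994% in the other masseter libraries.

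The 53 symbols in the column without a heading, whose origin and relation to these libraries are not stated and of which 20 are in the fixed lists, had a median of 0.45 in digastric (camera p = 2.3e-05, 0.365 with an estimated correlation) and 0.68 in masseter (p = 3.2e-16, 0.0987 with an estimated correlation). Of them, 1 gene was higher in digastric and 0 in masseter by limma over all genes. Their score in KPC replicates 1 to 3 was 0.49, -0.07 and 0.98 in digastric and 0.77, 0.03 and 1.37 in masseter.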
